A study of Mus musculus with 2 samples.

How the data were processed

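Whole-lung RNA of 2 groups of C57BL/6 mice was compared on 2 expression arrays, 1 with LLC cells carrying an empty vector and 1 with LLC cells overexpressing TDAG8. Per the labels' protocols, total RNA of 10 lungs was pooled for each array, and 2 µg of it was turned into biotin-labelled, fragmented cRNA by the Affymetrix procedure, which primes from the poly(A) tail and so reads transcripts near their 3′ end. The values deposited by the authors are intensity values, 1 per probe set, on a linear scale. Each column has a trimmed mean of 100 after leaving out 2% of the probe sets at each end, so each array had been scaled to a common target. The software that turned scanner images into intensities is not given in the sources used here, and the values came without detection calls. Both columns matched a labelled sample by name, and 0 columns were left over.

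Each column held 45101 probe sets, of which 64 control probe sets were set aside and 45037 used. In the platform annotation 34945 of these had 1 gene symbol, 932 had several and 9160 had none. Only those with 1 gene symbol were used for named genes, and 34741 of them were matched by gene identifier to the RefSeq gene table of assembly GRCm38.p6 for current symbols and chromosomes. No coordinates are given, because the files name no genome build. Where a gene had several probe sets, the one with the highest mean log2 intensity stood for it, which left 18193 genes. The floor for dim signals was the 50th percentile of each array, 26.3 in the vector control and 24.3 in the TDAG8 array. Lower values were raised to the floor, so a ratio against such a value is a lower bound, written as at least N-fold. Genes below the floor on both arrays were left out, which left 11949 genes, 905 of them above it on only 1 array.

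The measure was the log2 ratio of TDAG8 over vector control. The column medians differed by -0.11 on the log2 scale, more than the limit of 0.1 set beforehand, so ratios were centred on the median over the 11044 genes above the floor on both arrays, a shift of -0.06. Folds are ratios after centring, and intensities are printed as deposited. No significance test was run and no p-value or standard error is given, because each group had 1 array. The bootstrap intervals in the closing section cover the choice of genes only. Genes were counted as higher or lower at a ratio of at least 2-fold.

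There were 45 gene lists: proton-sensing receptors, cAMP and CREB response, proliferation, tumour-associated, hypoxia and glycolysis and pH genes, and markers of lung, vessel, stromal, muscle, fat, blood and immune cells. Other lists held interferon, inflammatory, acute phase, stress, clock, sex-linked, ribosomal, mitochondrial and reference genes. For a list with at least 4 measured members, the median log2 ratio was set against 10000 random lists of the same size, drawn from 20 bins of mean log2 level. A list stood apart where its median lay under percentile 2.5 of those medians or as far into the upper end. The same was done for the genes of each chromosome. Some genes belong to more than 1 list, and the percentile describes these 2 arrays only, since genes of a list are correlated.

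The lists, the floor, the limits and the rule for named genes were fixed before the data were examined. The rule named Gpr65 and the other proton-sensing receptors, the 12 genes with the highest and the 12 with the lowest ratio above the floor on both arrays, and the 4 largest bounds in each direction. It also named the 3 members of each list with the largest differences with its brightest member, and Actb and Gapdh. Genes known only by a clone or locus name were counted but not named. One item under this rule is not reported here.

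The procedure was tested on data simulated for this comparison from this series, with 11843 genes above the floor, noise of SD 0.496 taken from the interquartile range of the real ratios and 200 genes changed. Among changed genes that stayed above the floor on both simulated arrays, 39 of 50 at a log2 ratio of 1.5 were counted as 2-fold higher, and 49 of 50 at 2.5. At -1.5, 37 of 42 were counted as lower, and at -2.5, 24 of 24. Of 11644 unchanged genes 494 were also counted as 2-fold different. Of 400 random lists of 20 genes 26 stood apart, 6.5% against the 5% set by the limits, and 39 of 40 lists of 10 genes with 5 raised ones stood apart as high.

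The counts of genes, the named genes and the list and chromosome medians were recomputed under 8 alternatives, changing 1 choice at a time, wherever the gene or at least 4 members of the list stayed measured. Genes named only as members of a list were not recomputed singly. Counts of probe sets with no single gene name were made under the main setting only. The alternatives were no centring, quantile normalization, loess centring (span 0.3), floors at the 30th and 65th percentile and an offset of the array's 50th percentile in place of the floor. The others were the mean over all probe sets of a gene, and only probe sets without the suffixes that mark sequence shared with other transcripts. For lists the mean of the members was a further alternative. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.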

Results

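Gene expression was measured in whole lungs of C57BL/6 mice, 6 to 8 weeks old, 19 days after Lewis lung carcinoma (LLC) cells had been injected into the tail vein. LLC is a mouse lung carcinoma line of C57BL origin, and its cells form tumours in the lung after intravenous injection. Each mouse received 500000 cells in 200 µL. The cells carried either an empty vector or overexpressed TDAG8, the product of Gpr65, a proton-sensing receptor that couples to the stimulatory G protein and raises cyclic AMP at acidic pH. RNA of 10 lungs was pooled per group, and each pool was measured on 1 Affymetrix array, so the 2 groups were represented by 2 arrays. With 1 array per group there was no replicate check, no test and no error on any single value, and the pools gave no spread between mice. Every difference below therefore describes these 2 pooled RNAs, and the number of arrays limits the precision. Both columns had a trimmed mean of 100 intensity units, with maxima of 10112 in the vector control and 8731 in the TDAG8 array. Of 18193 genes with a probe set of their own, 11949 lay above the intensity floor on at least 1 array and 11044 on both. Across those 11044 genes, which are not independent replicates, the log2 intensities of the 2 arrays had a Pearson r of 0.936. The log2 ratio of TDAG8 over vector control had an SD of 0.55 across the same genes.

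The overexpressed gene was examined first, because its level bears on the sample labels. Gpr65 had an intensity of 32.3 in lungs with vector control cells and 73.9 in lungs with TDAG8-overexpressing cells, a log2 ratio of 1.25 or 2.38-fold. It was read by 1 probe set close to the floor. The species and extent of the transfected TDAG8 sequence are not given in the sources used here, so whether this mouse probe set reads it is unknown, and the value is no firm check of the labels. With the floor at the 65th percentile of each array the control value lay below the floor, and the log2 ratio had a lower bound of 0.29. Of the other proton-sensing receptors, Gpr4 went from 36.3 to below the floor and was at least 1.43-fold lower. Both probe sets of Gpr132 lay below the floor on both arrays. The 16 measured members of the cAMP and CREB response list had a median log2 ratio of -0.19, at percentile 8.25 of random lists. Most are targets downstream of the stimulatory G protein, but the list also holds Creb1 and Crtc2, factors of the pathway itself. The RNA was of whole lungs, so the list cannot tell whether the receptor was active in the tumour cells. With the mean over all probe sets of each gene the median was -0.412, at percentile 0.37, and stood apart as low. None of the 16 genes was counted as 2-fold different. The largest differences in that list were those of Rgs1, at least 1.99-fold higher, Per1 at -0.77 and Btg2 at -0.75, and the brightest member, Dusp1, was at -0.45.

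The lungs with TDAG8-overexpressing cells had more genes with higher than with lower expression. In all, 646 genes were at least 2-fold higher, 5.41% of those measured, and 142 were at least 2-fold lower, or 1.19%. At 4-fold the counts were 86 higher and 1 lower. The gene with the highest ratio was Fosl1, a subunit of the AP-1 transcription factor, which went from 27.2 to 320.0 intensity units, 12.3-fold. Its control value lay just above the floor of 26.3, so the log2 ratio of 3.61 became a lower bound of 2.41 with the floor at the 65th percentile, and a second probe set, below the floor in the control, gave a lower bound of 1.70. Egln3, an oxygen-sensing prolyl hydroxylase induced by hypoxia, was 9.35-fold higher. The monocyte chemoattractants Ccl7 and Ccl2 were 7.75-fold and 7.02-fold higher, Ccl2 going from 126 to 849. Rhox5, an X-linked homeobox gene active in testis, placenta and tumour lines, went from 276 to 1746, 6.60-fold. The proto-oncogene Myc was 6.42-fold higher, from 162 to 998.5, and the metalloreductase gene Steap1 was also 6.42-fold higher. The mitotic genes Bub1, Kif2c, Cdk1 and Cdca8 were between 5.75-fold and 6.52-fold higher, and the matrix glycoprotein gene Emilin2 was 5.72-fold higher. Among genes below the floor in the control array, Bcat1, a branched-chain amino acid transaminase, was at least 7.59-fold higher. The neuronal intermediate filament gene Prph was at least 6.52-fold higher, the homeobox gene Hoxa9 at least 6.10-fold and the mitotic kinesin gene Kif20a at least 5.52-fold. A second probe set of Hoxa9 was also below the floor in the control and gave a lower bound of 0.24 on the log2 scale. All other probe sets of Prph lay below the floor on both arrays.

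The lowest ratio was that of Clca1, a secreted protein of goblet cells, which went from 114 to 27.4 and was 4.01-fold lower. Retnla, a resistin-like protein of airway epithelium and alternatively activated macrophages, went from 2281 to 825, 2.66-fold lower, and was the brightest of the 12 lowest genes. The imprinted noncoding RNA Meg3 had a log2 ratio of -1.69, Fam107a -1.55, Lbh -1.45 and Rbmxl2 -1.42. Smim27 was at -1.38, Mturn at -1.37, Septin3 at -1.34, Kank1 at -1.31 and Dapp1 at -1.30. Myb, a transcription factor of blood progenitors, went from 256 to 97.3, a log2 ratio of -1.33. Other probe sets of Meg3, Lbh and Dapp1 gave values up to -0.15, 0.11 and 0.24. Genes above the floor in the control array alone included Zg16, a zymogen granule protein of goblet cells, at least 2.68-fold lower. Tnn was at least 2.62-fold lower, Ctsf at least 2.43-fold and Rbfox3 at least 2.37-fold. Of 199 higher genes with further probe sets above the floor on both arrays, 188 had the same sign by the median of those probe sets and 113 were at least 2-fold higher by it too. Of 38 such lower genes 37 had the same sign and 6 were at least 2-fold lower. The count of lower genes ranged from 31 with an offset on the log scale to 345 with the floor at the 30th percentile, and that of higher genes from 419 to 876. In simulated arrays with noise set from the interquartile range of the observed ratios, an SD of 0.496, 494 of 11644 unchanged genes passed 2-fold in either direction. That noise includes real differences and was the same at every level, so the count is no error rate for these arrays. With 1 array per group a single gene near that limit has little weight.

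**Figure D1:**
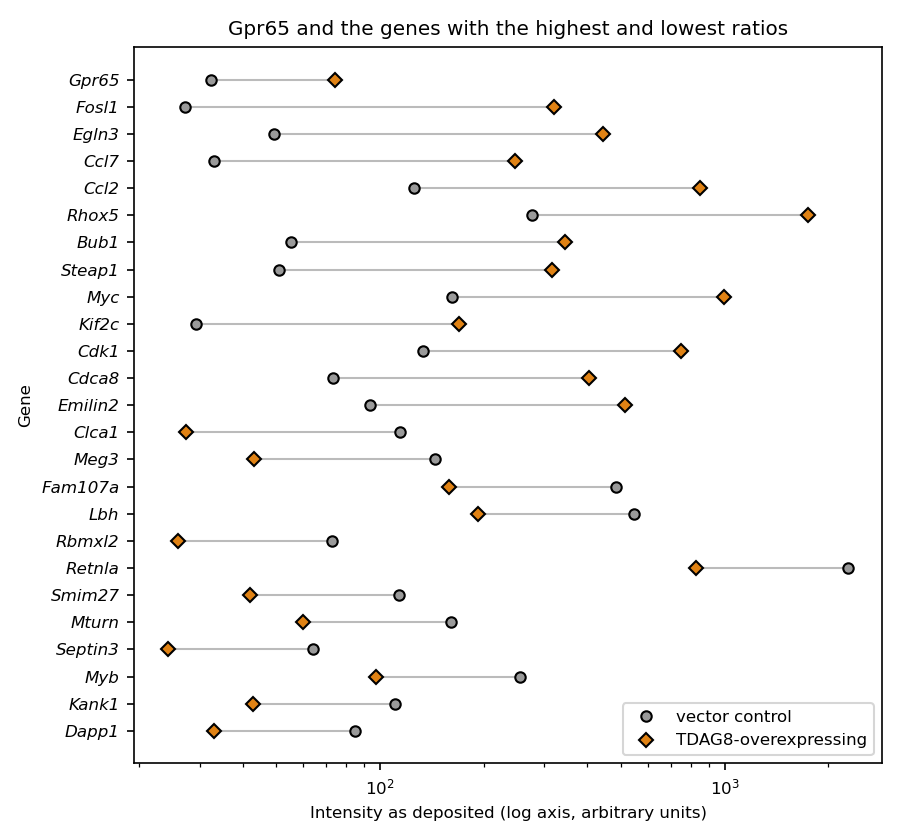
Intensity as deposited (log axis, arbitrary units) of Gpr65 and of the 12 genes with the highest and 12 with the lowest ratio, 1 gene per line. Circles are the vector control array and diamonds the TDAG8 array, each a pool of 10 lungs, and Fosl1 shows the widest gap, from 27.2 to 320.0.

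**Figure D2:**
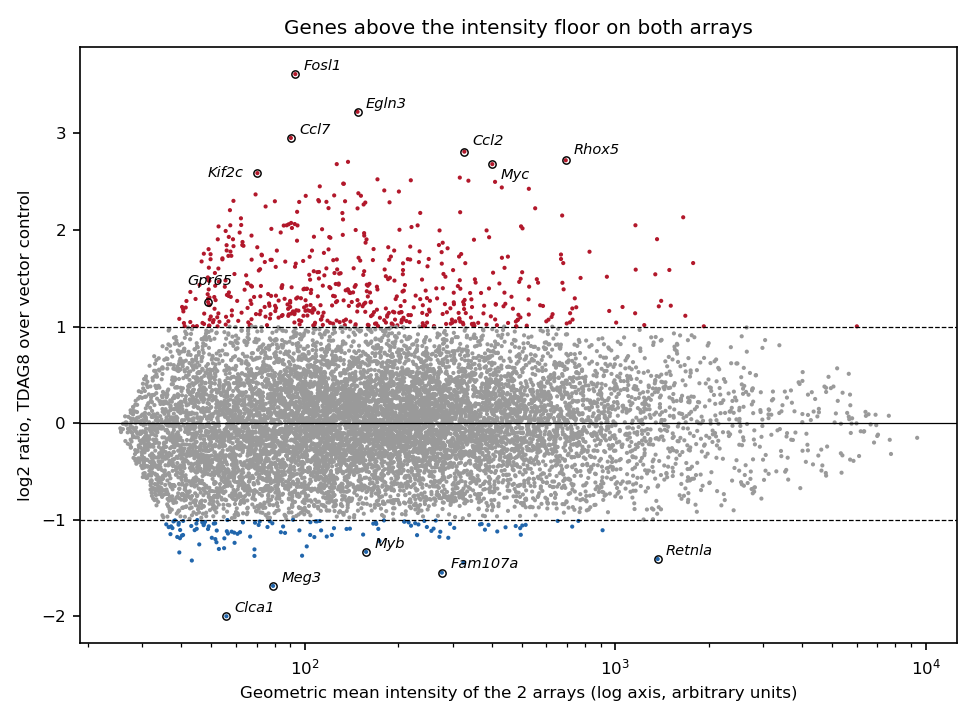
The log2 ratio of TDAG8 over vector control (vertical axis) against the geometric mean intensity of the 2 arrays (log axis, arbitrary units) for the 11044 genes above the floor on both. Red points are at least 2-fold higher (548 genes), blue points at least 2-fold lower (120 genes), and dashed lines mark the 2-fold limits.

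Cell cycle genes formed the group with the highest median. All 46 measured members of the proliferation list had ratios above 0, and 43 of them were at least 2-fold higher. Their median log2 ratio of 1.97 lay at percentile 100 of random lists matched on level. Of the 46 genes 5 were above the floor in the TDAG8 array only, which largely fixed the sign of their ratios. Bub1, a kinase of the spindle checkpoint, went from 55.1 to 345, Cdk1, the kinase that drives entry into mitosis, from 134 to 748, and Cdca8, of the chromosomal passenger complex, from 73.0 to 403. Pcna, the replication clamp and brightest member, went from 1206 to 2173, a log2 ratio of 0.91.

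In the list of tumour-associated and oncofetal genes 10 of 14 members were above 0 and 4 below, 7 were at least 2-fold higher, and the median log2 ratio was 0.78 at percentile 100. Of 22 listed genes only these 14 were measured. Among the 7, the 3 genes Twist1, Igf2bp3 and Afp were above the floor in the TDAG8 array only, which largely fixed the sign of their ratios. The 4 members below 0, named because they are the exceptions, were the embryonic growth factor gene Igf2 at -0.48, Mdk at -0.22, Gpc3 at -0.19 and Peg3 at -0.15. S100a4, a calcium-binding protein of motile mesenchymal cells, went from 808 to 3399, 4.38-fold. Twist1, a mesenchymal transcription factor, was below the floor in the control and at least 4.18-fold higher, Myc was at 2.68, and Cald1, the brightest member, was at 0.40. With the mean over all probe sets of each gene, the median of this list was 0.247 and lay inside the range of random lists.

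The joint list of genes induced by low oxygen and genes of glycolysis was higher as a group. Of its 26 members 22 were above 0, 10 of them at least 2-fold, with a median log2 ratio of 0.74 at percentile 100. The 4 members below 0, named because they are the exceptions, were Vegfa at -0.64, going from 935 to 577, Pfkfb3 at -0.51, P4ha2 at -0.25 and Egln1 at -0.17. Besides Egln3, the glucose transporter gene Slc2a1 went from 197 to 754, 3.99-fold, and Adm, the hypoxia-induced peptide adrenomedullin, from 43.1 to 163, 3.93-fold. Ldha, which makes lactate from pyruvate, went from 1392 to 2678, 2.00-fold. The list of pH regulation and proton transport genes did not stand apart, with a median of -0.01 at percentile 47.6 and 7 of 14 members above 0. Within it the lactate and proton cotransporter genes Slc16a3 and Slc16a1 were 3.07-fold and 2.74-fold higher. Car4, a membrane carbonic anhydrase of lung capillaries, was at -0.78, and Bsg, the chaperone of the lactate transporters, at 0.07.

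Genes that mark the resident cells of the lung were lower, by less than 2-fold in most cases. All 16 alveolar type 1 genes, all 14 club cell genes, all 22 ciliated cell genes and all 26 endothelial genes had ratios below 0, except that 2 ciliated cell genes lay above 0 after loess centring and 1 club cell gene lay at 0 after quantile normalization. Their medians were -0.58, -0.62, -0.80 and -0.74, each at percentile 0. Of the 18 alveolar type 2 genes 17 were below 0, with a median of -0.43 at percentile 0.06. At least 2-fold lower were 5 ciliated and 1 endothelial gene and no alveolar type 1, alveolar type 2 or club cell gene. The surfactant gene Sftpc, the brightest type 2 member, was at -0.12, while Chia1 was at -0.74, Napsa at -0.58 and Lpcat1 at -0.58. Ager, the type 1 membrane receptor, went from 6541 to 4397, a log2 ratio of -0.51, with Col4a4 at -0.87, Clic5 at -0.81 and Spock2 at -0.78. Scgb1a1, the club cell secretory protein, was at -0.15, whereas Cyp2b10 went from 1782 to 856, Cyp4b1 was at -0.90 and Fmo2 at -0.85. Among ciliated cell genes Fam183b was at -1.16, Tppp3 at -0.76, and Tekt2 and Dnah5 were at least 2.34-fold and 2.16-fold lower.

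Lists for vessel, muscle and lining cells had medians below 0 as well. In the endothelial list Clec14a went from 1077 to 491, a log2 ratio of -1.07, Robo4 was at -0.91, Plvap at -0.89 and Thbd at -0.62. The 6 lymphatic endothelial genes had a median of -0.66 at percentile 0.1, with Lyve1 at -0.90, Reln at -0.76 and Mmrn1 at -0.73. With the mean over probe sets that median was -0.503 and no longer stood apart. Smooth muscle and pericyte genes had a median of -0.58 at percentile 0.01, with 13 of 14 below 0. The smooth muscle myosin gene Myh11 was 2.24-fold lower, Notch3 was at -0.97, Synpo2 at -0.81 and Acta2 at -0.30. Mesothelial genes had a median of -0.43 at percentile 0.385, led by Krt19 at -0.87, Krt7 at -0.66 and Upk1b at -0.64, while the brightest, Krt8, was at 0.59. Cardiac muscle genes, which in mouse lung come from the sleeves of the pulmonary veins or from attached heart tissue, had a median of -0.59 at percentile 0.01. Myh7 was at -0.97, Tnni3 at -0.93, Hrc at -0.82 and Actc1 at -0.71.

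Genes of matrix and vessel growth went both ways. Of 29 fibroblast and extracellular matrix genes 15 were below 0 and 14 above, and the median of -0.24 lay at percentile 1.06. The members with the largest differences were all higher: Col6a3 went from 928 to 2060, Lum was 2.20-fold and Col5a1 2.19-fold higher, whereas Sparc, the brightest, was at -0.34. The mean of this list was 0.04, of opposite sign to its median. The median was inside the range of random lists after loess centring (-0.199), with the lower floor (-0.153), with the mean over probe sets (-0.133) and without probe sets that can share sequence (-0.234). The angiogenesis list had a median of -0.34 at percentile 0.94 with 10 of 15 members below 0, and its mean of -0.05 did not stand apart. Hif1a, the oxygen-regulated transcription factor subunit, went from 926 to 2138, a log2 ratio of 1.27, with Pgf 2.01-fold higher and Nrp2 at 0.85. Its endothelial relative Epas1 was at -0.34. Protease and invasion genes had a median of 0.47 at percentile 99.9 with 14 of 19 above 0. Timp1, an inhibitor of metalloproteinases, was 4.01-fold higher, Adam8 3.01-fold and the membrane metalloproteinase gene Mmp14 2.27-fold, with Ctsb at 0.52. That median was 0.118 with the floor at the 65th percentile and 0.208 without probe sets that can share sequence, both inside the range of random lists.

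Myeloid and inflammatory genes were higher. Of 24 monocyte and macrophage genes 21 were above 0 and 13 at least 2-fold higher, with a median log2 ratio of 1.06 at percentile 100. The scavenger receptor gene Msr1 was at least 4.85-fold higher, the integrin gene Itgam 3.32-fold and the high-affinity Fc receptor gene Fcgr1 3.28-fold, while the brightest member, the lysozyme gene Lyz2, was at -0.09. All 19 inflammatory cytokine and chemokine genes were above 0 and 8 were at least 2-fold higher, with a median of 0.66 at percentile 100, and 18 lay above 0 without centring or after quantile normalization. Of the 19 genes 5 were above the floor in the TDAG8 array only, which largely fixed the sign of their ratios. Beside Ccl7 and Ccl2, Saa3 was 4.13-fold higher, and Il33, the brightest, was at 0.14. All 27 interferon response genes were above 0 and 7 were at least 2-fold higher, with a median of 0.61 at percentile 100. Oas1a, a sensor of double-stranded RNA, was at 1.58, Zbp1 at 1.41, Oas2 at 1.32 and Gbp2 at 0.61. Of 15 neutrophil genes 12 were above 0, with a median of 0.45 at percentile 99.3. Clec4d was 4.67-fold, Padi4 at least 2.93-fold and Il1b 2.82-fold higher, and Chil1 was at -0.36. S100a9 was at 0.28, S100a8 at 0.10, Mmp9 at 0.09, Lcn2 at -0.12 and Ltf at -0.56. Of the 15 genes 5 also belong to other lists, and 3 were above the floor in the TDAG8 array only. The median of the neutrophil list was 0.256 and inside the range of random lists with the floor at the 65th percentile.

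Lists for alveolar macrophages and for alternative activation were summarised separately. The 15 alveolar macrophage genes had a median of -0.34 at percentile 1.6, of which 7 also belong to other lists. Fabp1 was 2.19-fold lower, Car4 was at -0.78, Chil3 went from 3662 to 2148, and the scavenger receptor gene Marco was 2.16-fold higher. That median was inside the range of random lists after quantile normalization (-0.337), after loess centring (-0.288), with the higher floor and with an offset. Alternative activation genes had a median of 0.16 at percentile 82.9, with 3 members at least 2-fold higher and 2 at least 2-fold lower. That median turned to -0.04 with either other floor, to -0.156 with the mean over probe sets and to -0.231 without probe sets that can share sequence, all inside the range of random lists. Arg1, the arginase of such macrophages, went from 72.1 to 333, a log2 ratio of 2.26, and Ccl8 was 2.38-fold higher, against Retnla at -1.41 and Chil3 at -0.71.

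B cell genes were lower, with 16 of 17 below 0 and a median of -0.47 at percentile 0.15. Ebf1, a transcription factor of the B lineage, was 2.46-fold lower, Fcmr was at -0.96, H2-Ob at -0.82 and the CD20 gene Ms4a1 at -0.64. T cell genes had a median of 0.02 at percentile 67.3, with Zap70 2.46-fold higher, Icos and Ctla4 at least 1.66-fold higher and Il7r at -0.22. Natural killer and cytotoxic genes had a median of 0.05 at percentile 78.5, with Klrk1 at 0.59, Gzma at -0.49, Gzmk at least 1.31-fold higher and Ccl5 at 0.20. Immunoglobulin and plasma cell genes were at -0.06 (percentile 42.5), MHC class II genes at 0.05 (percentile 58.6), dendritic cell genes at -0.23 (percentile 10.8) and thymocyte genes at -0.23 (percentile 23.9). In the dendritic cell list the actin-bundling gene Fscn1 was 4.44-fold and Bst2 2.09-fold higher and Ccl22 was at -0.83. The invariant chain gene Cd74 was at 0.03. The medians of the T cell, natural killer, immunoglobulin and MHC class II lists changed sign with the scaling of the arrays.

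Among general cell functions, heat shock genes were higher, 10 of 11 above 0, with a median of 0.57 at percentile 99.9. The chaperone genes Hsph1, Hspd1 and Hspe1 were 2.28-fold, 2.16-fold and 1.95-fold higher, and Hspa8 was at 0.57. Circadian clock genes were lower, with a median of -0.53 at percentile 0.01 and 13 of 17 below 0. Tef was 2.02-fold lower, Usp2 was at -0.91, Nr1d2 at -0.59, and Nfil3, which represses at the sites where Tef activates, was at least 2.67-fold higher. Immediate early genes had a median of -0.08 at percentile 23.7, with Socs3, the feedback inhibitor of cytokine signalling, 3.59-fold higher, Myc as above, Junb at 0.88 and Dusp1 at -0.45. Ribosomal protein genes had a median of 0.24 at percentile 96.6 and oxidative phosphorylation genes of 0.23 at percentile 97.3, both short of standing apart. Reference transcripts had a median of 0.21 at percentile 85.8. Among them Actb was at -0.09, whereas the glycolytic enzyme gene Pgk1 went from 881 to 2538, Tubb5 was at 0.81 and Gusb at 0.56. Gapdh had no probe set of its own besides the array's control probe sets, since others also match related loci, and the log2 ratios of the control probe sets before centring were 0.83, 0.86 and 1.06.

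**Figure D3:**
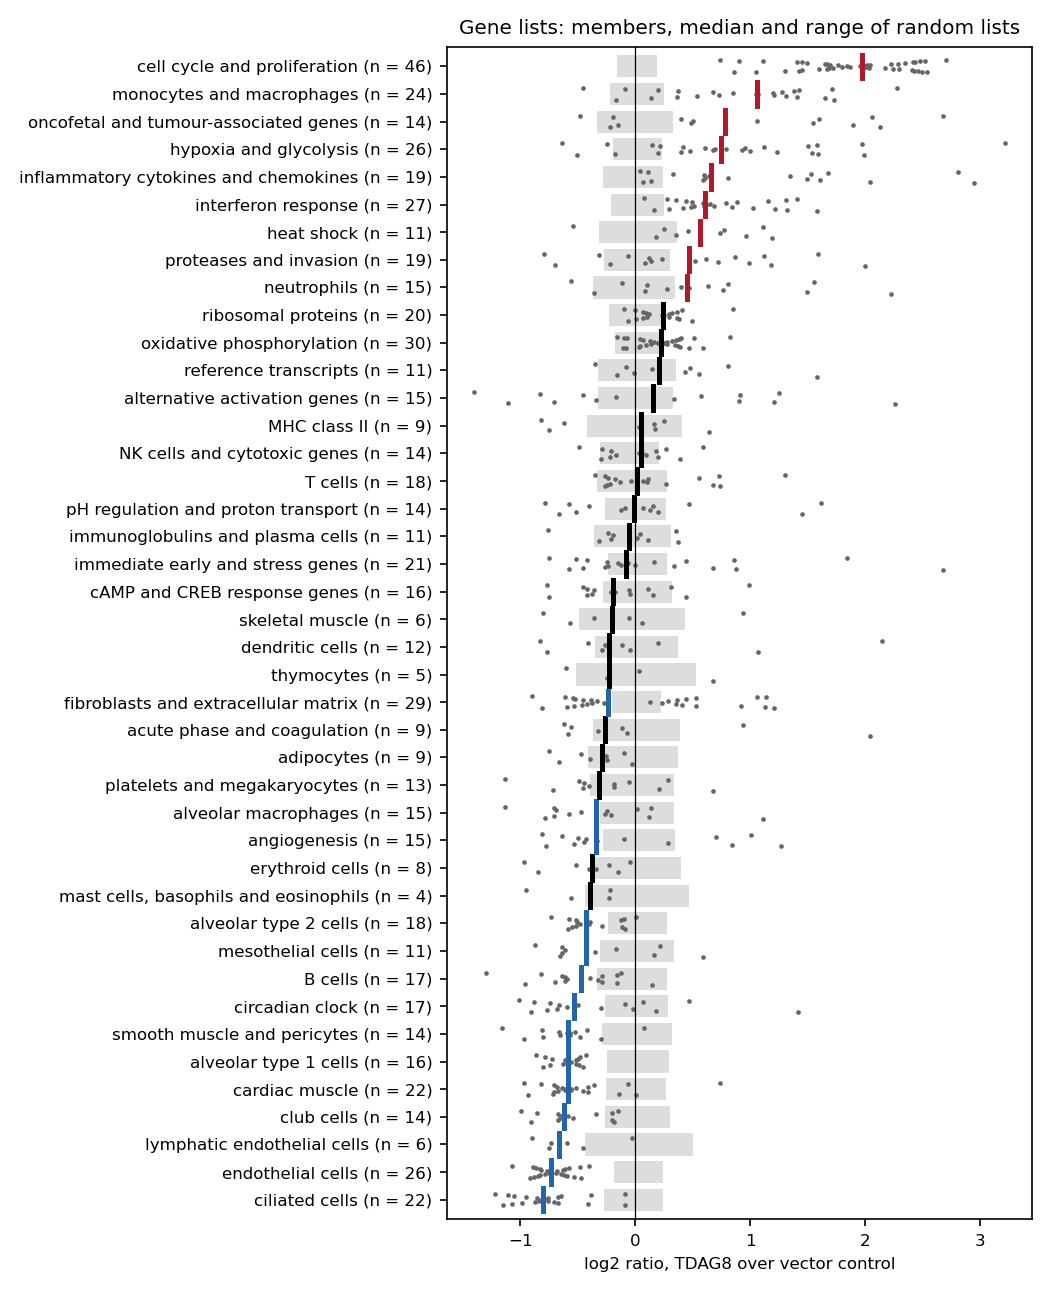
The log2 ratio of TDAG8 over vector control (horizontal axis) for 42 gene lists, 1 list per line, with points for the members, a vertical line for the median and a grey bar for the central range of medians of 10000 random lists matched on level. Red medians lie above that range (9 lists), blue below it (14 lists) and black inside it (19 lists), with cell cycle genes highest at 1.97 and ciliated cell genes lowest at -0.80.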

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

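Probe sets with no single gene name entered no comparison above. Among 2917 of these above the floor on at least 1 array, 97 were at least 2-fold higher in the TDAG8 array, 3.33%, and 32 were at least 2-fold lower, 1.10%. They stand here because they are a signal above the control array in data not otherwise used, where the shares of named genes were 5.41% and 1.19%. Which transcripts they read was not analysed here.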

How the results depend on the processing

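No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out and no other split of the samples exists. Over the 8 alternatives for counts, the genes at least 2-fold higher numbered 419 with the floor at the 65th percentile and up to 876 at the 30th, against 646, and 419 and 646 of these were also in the main count. Genes at least 2-fold lower numbered 345 and 68 with those floors and 31 with an offset, against 142, as a lower floor admits dimmer genes and an offset shrinks ratios of dim genes. Higher genes made up 82.0% of all those counted, 71.7% with the lower floor, 93.3% with the offset and 73.6% without centring. The log2 ratio of Gpr65 was 0.29 with the floor at the 65th percentile, a lower bound because its control value lay below that floor, and no lower than 0.81 in the other alternatives. Of 373 list medians under alternatives 343 kept their side of the limits, 14 moved inside them, 15 moved outside and 1 reversed. Among the 343, the sign turned in 22, all from 9 lists that did not stand apart, such as T cells, MHC class II and alternative activation. Of the lists that stood apart, 6 of 9 high and 10 of 14 low ones did so in every alternative. Calls that ended were those for alveolar macrophages (quantile -0.337, loess -0.288, higher floor -0.288, offset -0.239), fibroblasts and matrix (loess -0.199, lower floor -0.153, mean over probe sets -0.133, without shared sequence -0.234), proteases (higher floor 0.118, without shared sequence 0.208), neutrophils (higher floor 0.256), tumour-associated genes (mean over probe sets 0.247), lymphatic endothelium (mean over probe sets -0.503) and angiogenesis (list mean -0.0537). The list mean of fibroblast and matrix genes reversed to 0.0435. Calls appeared for erythroid genes (quantile -0.411, loess -0.335, mean over probe sets -0.366, list mean -0.440), oxidative phosphorylation (quantile 0.147, list mean 0.219), mast cells, basophils and eosinophils (loess -0.415, offset -0.470, mean over probe sets -0.403, list mean -0.489), platelets (lower floor -0.409, mean over probe sets -0.368), cAMP and CREB response (mean over probe sets -0.412) and adipocytes (mean over probe sets -0.374, list mean -0.357). For lists the cause was not tested. The pooled median of the 7 resident lung lists, under alternatives chosen after seeing the data, lay between -0.692 and -0.558. Single genes were recomputed for those with the highest and lowest ratios, the largest bounds, Gpr4 and Actb, but not for genes named only as list members. Of their 258 log2 ratios under alternatives 226 stayed within 1.5-fold of the main ratio, 32 moved further and 0 reversed. Most of these genes were picked for extreme ratios in the same data, so a reversal was unlikely from the start. Reversal was counted only for genes at 2-fold or more in the main setting. Signal near the floor limits the bounds and the dimmest genes, and no detection calls were used here.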

Other observations

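All checks of explanations below, and the gene groups of the first paragraph, were chosen only after the values were seen. The bootstrap intervals below resample genes, which are correlated, and measure no spread between mice or arrays. The Hox genes are given by paralogue group as values only, without a test. Of 8 measured genes of paralogue groups 1 to 7, the groups that pattern the anterior trunk and lung, all were below 0, from -0.02 for Hoxb4 to -0.92 for Hoxb5, with Hoxa5 going from 391.5 to 239.6. Hoxb4 lay above 0 after quantile normalization or loess centring, and at 0.00 without probe sets that can share sequence. All 5 measured genes of groups 8 to 13 were at least 2-fold higher: Hoxd8 5.16-fold, Hoxd9 4.15-fold, and Hoxa9, Hoxd10 and Hoxa10 at least 6.10-fold, 2.82-fold and 2.02-fold. The last 3 of these, and Hoxa4 and Hoxb6 among the lower genes, were above the floor on only 1 array, which largely fixed the sign of their ratios. At 2-fold or more were 4 of 5 without centring or with an offset, and 3 of 4 with the floor at the 65th percentile. Besides Clca1 and Zg16, the intestinal goblet cell genes Lgals4 and Muc2 were at least 2.15-fold and 2.10-fold lower and Fcgbp was 1.84-fold lower. Zg16, Lgals4 and Muc2 were above the floor in the control array only. These 5 genes were picked by their values, so they say nothing of goblet cells as a group, and with the floor at the 65th percentile 0 of the 3 still measured were 2-fold lower. Of 8 genes of serine synthesis and one-carbon metabolism 5 were at least 2-fold higher, against 4 of 8 with the mean over probe sets and 2 of 5 without probe sets that can share sequence. Shmt2 was 3.55-fold, Psat1 3.53-fold, Phgdh 3.43-fold, Mthfd2 2.89-fold and Mthfd1l 2.70-fold higher, while Shmt1 was at -0.01. The noncoding gene Pvt1, the neighbour of Myc, went from 57.8 to 309 on its brightest probe set, and all 5 of its probe sets were higher. Those with control values of 20.5, 20.2 and 9.2 were below the floor there, and the last reached only 26.9 in the TDAG8 array.

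Other lists fixed before the data were examined did not stand apart, or had too few measured members to be set against random lists. Erythroid genes had a median log2 ratio of -0.37 at percentile 2.59, with all 8 members below 0, among them Hbb-b2 at -0.97, Alas2 at -0.85, Car2 at -0.52 and Tfrc at -0.05. Mast cell, basophil and eosinophil genes were at -0.39 (percentile 3.74), with Kit at -0.95 and Gata2 at -0.56. Platelet genes were at -0.32 (percentile 5.95), with Tubb1 2.20-fold lower and Pf4 1.60-fold higher. Acute phase and coagulation genes were at -0.26 (percentile 7.91), with Saa3 4.13-fold higher, F10 at 0.94, Cp at -0.63 and Hp at -0.59. Adipocyte genes were at -0.29 (percentile 8.81), with Lipe at -0.75, Adipoq at -0.66 and Scd1 at -0.10. Skeletal muscle genes were at -0.21 (percentile 24.99), with Acta1 at least 1.91-fold higher and Car3 at -0.57. Of the squamous list 3 genes were measured, Lor at 0.46, Krt10 at 0.24 and Ltf at -0.56. Of the sex-linked list, Xist went from 2906 to 2021, a log2 ratio of -0.47, and Eif2s3y, a Y-linked gene below the floor in the control, was at least 1.48-fold higher. The other probe set of Eif2s3y, and all those of the Y-linked genes Uty and Kdm5d, lay below the floor on both arrays. Median log2 ratios of whole chromosomes lay between -0.11 (X) and 0.10 (4), with 6 of 20 chromosomes above and 5 below the range of random lists.

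The first pattern weighed was that proliferation and tumour-associated genes were higher while genes of resident lung cells were lower. Scaling was argued against by the gap between the cell cycle median and the pooled lung median, which a uniform factor cannot change and which was 2.63 after quantile normalization and 2.61 after loess centring, and RNA integrity by a log2 difference in 3′ over 5′ ratio of at most 0.126 for Actb and Gapdh. Faster cycling in an unchanged tumour mass, as the whole cause, would leave lung genes unchanged. Their pooled median was -0.620 (95% bootstrap interval over genes -0.671 to -0.573). It covered 132 genes of the type 2, type 1, club, ciliated, endothelial, smooth muscle and cardiac lists. The median was -0.581 over 155 genes without the cardiac and with the lymphatic, mesothelial and fibroblast lists. These lists are part of the pattern itself and were pooled after their values were seen. The values therefore show only that faster cycling alone leaves the lower lung genes unexplained. A larger share of tumour tissue in the lungs with TDAG8-overexpressing cells may account for both sides and stays an untested hypothesis, because the tumour-associated median of 0.780 (0.247 with the mean over probe sets, inside the range of random lists) is part of the pattern itself. Whether a few of the 10 mice set the pattern stays open too, as pools hide the spread between mice.

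The second pattern was that endothelial genes were lower than alveolar type 2 genes, by -0.313 in median log2 ratio (95% bootstrap interval over genes -0.507 to -0.162; -0.315 to -0.173 over 8 alternatives). Compression of very bright signals may account for part of it, because the gap without probe sets of mean intensity of at least 4000 was -0.247 and its interval, -0.478 to -0.118, spans 50% of the full gap. Equal dilution of every lung lineage together with such compression therefore stays open, although the upper bound of -0.118 lies below 0, and these lists were set side by side because they differed. The type 2 median of -0.43 was the highest of the 7 resident lung lists. The ciliated median of -0.80 lay below the endothelial one of -0.74, with club cells at -0.62, cardiac muscle at -0.59 and type 1 cells and smooth muscle at -0.58. Lower values than in type 2 genes were therefore not particular to vessels. A further loss of vessel transcripts stays a hypothesis that 1 array per group cannot test.

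The third pattern was the higher Gpr65 signal, at a log2 ratio of 1.25. Receptor transcripts of monocytes and macrophages are a candidate source that was not tested. In that list 37.5%, 9 of 24 genes, had ratios at or above that of Gpr65. This does not single out those cells, as the median of the cell cycle list, 1.97, also lay above the Gpr65 ratio. Of those 24 genes 22 were above the floor in the control lungs too, 3 belong to another list, and the member with the brightest probe set, Lyz2, was at -0.09. Its intensities, 6650 in the control and 6002 in the TDAG8 array, lie above the limit of 4000 used for very bright signals. Its ratio may therefore be compressed and says little about these cells. The leukocyte gene Ptprc went from 891 to 964 on its brighter probe set, a log2 ratio of 0.17. As 1 gene on arrays scaled to a common target, it cannot tell whether the number of leukocytes differed. The transfected sequence cannot be told apart from this source, because Gpr65 was read by 1 probe set and whether it reads that sequence is unknown.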
